A study of Homo sapiens with 4 samples.

How the data were processed

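OGA CUT&Tag was measured in H9 human embryonic stem cells in naive culture, with 2 libraries from control cells and 2 from cells with OGA knockdown. Groups and replicate numbers were taken from the sample labels. The submitters' processing notes name Bowtie2 2.3.4.3, SEACR 1.3, ChIPseeker 1.12.1, DESeq2 and edgeR and the genome build GRCh38.p13, with no role or order. The role of each tool, the antibody control, the peak threshold and the sequencing depth were not given in the sources used here.

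The authors deposited 1 annotated list of regions per group, 2 lists in all. Per the file headers each line gives position, width in base pairs, annotation class, signed distance to the nearest transcription start site in base pairs, transcript and gene. A further column names the numbered peaks of each replicate behind a region, and every region named peaks of both replicates. A region is therefore a merged interval, and its width is that of the merged interval as the authors listed it. The deposited lists carry no count, signal, score or p-value per region. Because the lists merge both replicates, no region had a value per library to average, test or leave out. The peak numbers give a lower limit for the peaks called in each library and on each chromosome, and hold no value of a region. The control list repeated 1 line, which was used once, leaving 8977 distinct regions from 8978 lines.

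Gene names were matched to a RefSeq gene table of assembly GRCh38.p14, used for current and older symbols, gene type, gene length and the order of neighbouring genes. Of 6510 gene names in the control list 6240 matched, and of 1178 in the knockdown list 1130. Coordinates are those of the deposited lists. The nearest start site decides the gene, so a region between divergent genes counts for 1 of them.

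Regions of the lists were compared by overlap of at least 1 bp. Chance overlap was taken from 100 random placements of the knockdown regions within the span of listed regions on the same chromosome. Shares carry Wilson 95% intervals, which cover counting error only. The 16 gene lists were fixed before the data were examined. For each, genes with a promoter region were counted and set beside 10000 random lists of the same size drawn from 20037 protein-coding genes and matched on 5 classes of gene length. These counts describe the lists and are no test of the knockdown. For genes with a promoter region in both lists, random sets of control genes were matched on 5 classes of region width, except in the analysis by gene type. That comparison, its repeat with any region assigned to a gene, and the use of the 97.5th percentile to count lists above chance were chosen after seeing the data, as were the analyses by gene type, pathway and chromosome. Across chromosomes, relations were given as Pearson's r and Spearman's rho with 100000 permutations, and Fisher's exact test was two-sided.

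The rule for named genes, fixed before the data were examined, took OGA and OGT, the 10 highest-scoring control promoter regions with a knockdown overlap, the 10 highest without, the 5 highest knockdown promoter regions without a control overlap, and up to 4 members of each list. As the lists hold no score, region width was used in its place, a choice made after the files were seen. Some genes that the rule names are not reported here. NANOG regions, the locus map, further list members and list genes with a knockdown region were named after their values were seen.

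Alternatives were regions at least as wide as the control median, equal numbers of regions, overlap of 50% of the shorter region, centres within 500 bp, promoters within 1 kb, primary chromosomes, regions of at least 200 bp, and any region assigned to a gene. Random lists without length matching and the removal of histone genes were added after the data were seen. The motif analysis was not run, since no genome sequence was used here. A test of read counts per region was planned with edgeR, which the submitters' notes also name, and was not run, since the deposited lists give no counts.

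The overlap step was tested on simulated data, where 300 of 300 planted overlaps among 1334 regions were recovered. For simulated lists of 30 genes among 20000, 185 of 200 lists drawn at random fell inside the central 95% of random lists, and 179 of 200 lists in which each gene had a 40% chance of a region lay above the 97.5th percentile. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.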

Results

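Chromatin occupancy of OGA, the enzyme that removes O-linked N-acetylglucosamine from nuclear and cytosolic proteins, was profiled by CUT&Tag in H9 human embryonic stem cells. H9 is an established embryonic stem cell line, and here it was kept in the naive state in PXGL medium, which combines inhibitors of MEK, tankyrase and protein kinase C with LIF, on mouse feeder cells. CUT&Tag directs a transposase to an antibody-bound protein, so that DNA near that protein is cut and tagged for sequencing. There were 4 libraries, 2 from control cells and 2 from cells with OGA knockdown. The deposited data were 1 list of annotated regions per group, and each region in a list named at least 1 peak from replicate 1 and at least 1 peak from replicate 2. The lists held no read counts, signals or scores, so the depth of the libraries was unknown and no region could be tested across replicates. The labels do not state that the replicates were separate cultures.

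OGA regions in control naive cells lay at the promoters of many genes of the pluripotency network. Of 14 core pluripotency genes, 11 had a promoter region in the control list, among them POU5F1, SOX2, SALL4, LIN28A and L1TD1, against a mean of 2.09 in 10000 random gene lists matched on gene length. Of 29 naive pluripotency genes, 12 had one, against a random mean of 4.09, and these included GDF3, a TGF-beta family ligand, DPPA3, DPPA5, DPPA4, FGF4 and UTF1. None of the 10000 random lists reached either count. Random genes were drawn without regard to position, however, while some naive genes are neighbours. Examples are GDF3 and DPPA3 on chromosome 12 and DPPA2 and DPPA4 on chromosome 3, which are not independent draws. The random lists were drawn from all protein-coding genes and were not matched on expression or chromatin accessibility. A preference for active promoters in general was therefore not separated from one for pluripotency genes. Promoter regions of naive genes were in part away from the start site: with promoters limited to 1 kb, the naive list no longer stood above the 97.5th percentile of random lists. Other naive markers, such as KLF17 and SUSD2, had no promoter region in control, and SUSD2 had 3 regions elsewhere.

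The region at POU5F1, which encodes OCT4, covered chromosome 6 positions 31170680 to 31173874 (GRCh38, 3195 bp) and included a transcription start site. The L1TD1 promoter region lay on chromosome 1 at 62195161 to 62199065 (3905 bp), and that of LIN28A at 26407991 to 26411201 of the same chromosome (3211 bp). The CRIPTO region, at the gene also known as TDGF1, lay on chromosome 3 at 46573621 to 46576631 (3011 bp). The GDF3 region was the widest among promoter regions of the naive list, on chromosome 12 at 7692176 to 7696994 (4819 bp). UTF1 had its region 1352 bp from the start site, on chromosome 10 at 133231569 to 133234165 (2597 bp). The regions of DPPA4 (2483 bp) and FGF4 (2423 bp) followed in width. NANOG had 5 control regions, of which 0 were annotated as promoter.

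Histone, ribosomal protein and chromatin regulator genes also carried OGA regions in control more often than random gene lists, again not matched on expression. Replication-dependent histone genes, which package newly made DNA, had a promoter region in 33 of 45 cases, against a random mean of 4.78. The widest, at H3C11, H2AC17, H4C6 and H2AC4, all lay on chromosome 6, where 20.7% of protein-coding genes had a promoter region. Random lists were matched neither on chromosome nor on gene clustering, so neighbouring histone genes were not independent draws. Cytosolic ribosomal protein genes had a promoter region in 30 of 76 cases (random mean 9.12), with the widest at RPS15A (3760 bp), RPL3 (3400 bp) and RPS25 (3201 bp). The list of polycomb and DNA methylation genes had 12 of 26 (random mean 3.99), including EZH2, the catalytic subunit of polycomb repressive complex 2, PHC1 and DNMT3B. For these 3 lists 0 of 10000 random lists reached the count. Glycolysis genes had 7 of 19 (random mean 2.87; 178 of 10000 random lists as large), with ENO2, HK2, LDHA and TPI1 the widest. Cell cycle and DNA replication genes had 11 of 29 (random mean 4.37; 19 random lists as large), with CDC25A, CCNB1 and ORC1 among the widest. The polycomb and DNA methylation list and the glycolysis list did not stay above the 97.5th percentile when only the widest control regions were used, and with regions at least as wide as the median the cell cycle list did not either.

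Markers of trophectoderm, germ layers and fibroblasts had few OGA promoter regions in control, within the range of random gene lists. Trophectoderm and trophoblast genes had 2 of 25, at TEAD4 and KRT8 (random mean 3.71; 2590 of 10000 random lists as small). Germ layer regulators had 2 of 24, at TBX6 and HOXB1 (random mean 3.19; 3580 as small), and fibroblast markers had 1 of 18, at SPARC (random mean 2.88; 1944 as small). Olfactory receptor genes had 0 of 28 (random mean 3.59; 212 of 10000 random lists as small), and genes of 8-cell-like cells had 0 of 19 (random mean 2.57; 627 as small). Primed pluripotency genes had 5 of 21, at DNMT3A, DNMT3B, NODAL, LEFTY1 and LEFTY2 (random mean 2.97; 1620 random lists as large). Mitochondrial respiratory chain genes had 10 of 55, the widest at ATP5MC1, SDHB, UQCRC2 and NDUFA11, with a random mean of 7.70 and 2340 random lists as large. ERK, WNT, PKC and LIF signalling genes had 7 of 37, the widest at STAT3, ETV4, PRKCZ and GSK3B, with a random mean of 5.60 and 3266 random lists as large. Among genes of O-GlcNAc cycling and the hexosamine pathway 7 of 24 had a promoter region (random mean 3.88; 786 random lists as large), including TET1, SIN3A, HK2 and NAGK. With any region assigned to a gene, the primed, O-GlcNAc cycling and signalling lists stood above the 97.5th percentile, at 9 of 21, 11 of 24 and 14 of 37. OGT, which encodes the transferase that adds the sugar, had a control region over a start site on the X chromosome at 71532331 to 71533477 (1147 bp), while no region in either list was assigned to OGA itself.

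**Figure D1:**
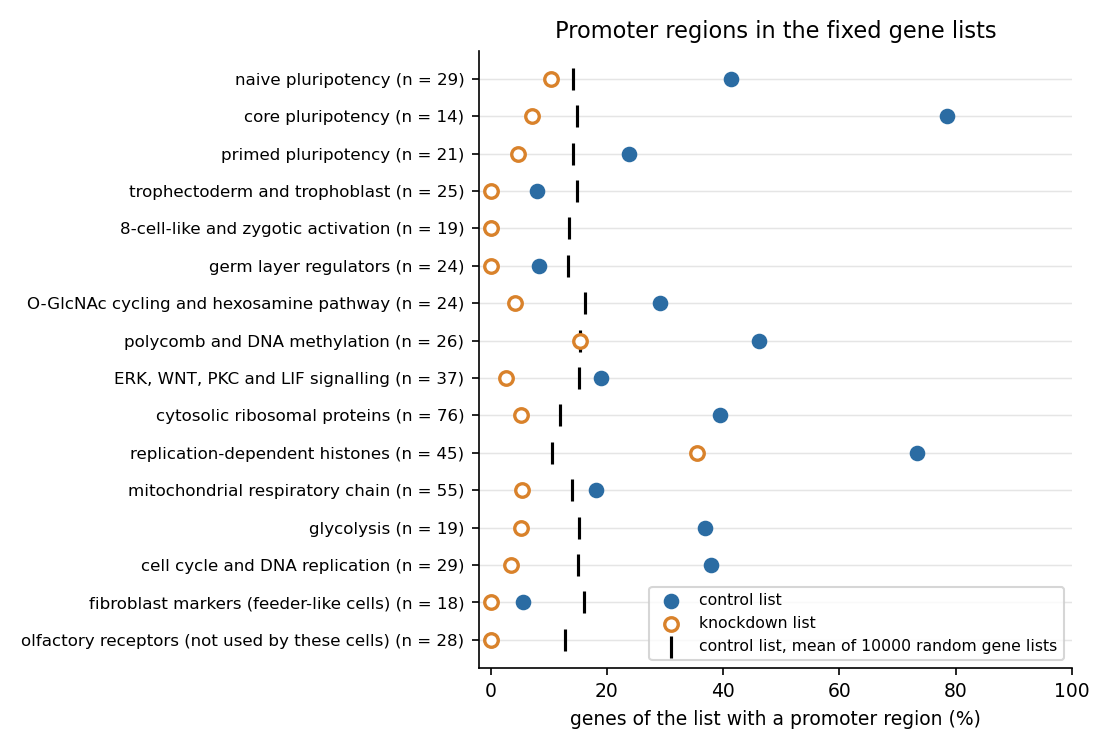
Share of the genes of each fixed list that had a promoter region (x axis, percent; n is the number of genes) in the control list (filled points) and the knockdown list (open points), with the mean of 10000 random gene lists for the control list as a vertical bar. Core pluripotency genes (11 of 14) and replication-dependent histone genes (33 of 45) lay far to the right in control, and 16 of the 45 histone genes had a region in the knockdown list.

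Control regions were next compared with those in the OGA knockdown list. A listed region needed a peak in both replicates. At most 9.53% and 9.72% of numbered knockdown peaks were in the list, against at most 38.5% and 32.5% in control. A gene without a knockdown region may therefore still have had a peak in a knockdown replicate, and dependence on OGA was not tested. Most genes with a control promoter region had none in the knockdown list, where 395 of 3810 had one (10.4%). Of the 11 core pluripotency genes with a control promoter region, 0 had a promoter region in the knockdown list, against a mean of 1.27 in random sets of control genes matched on region width (2543 of 10000 sets also had 0), although a knockdown region overlapped the control region at L1TD1. Of the 12 naive genes 3 had one in both lists, DNMT3L, DPPA2 and NLRP7, against a random mean of 1.42 (1587 of 10000 sets as large). With any region assigned to a gene, 8 of the 29 naive genes were in the knockdown list, against 0.984 in random gene lists, and 0 of 10000 random lists reached 8. Of the 18 naive genes with any control region 7 were also in the knockdown list (38.9%), against 3.40 in random sets of control genes matched on width (390 of 10000 as large), and of 13 core genes 3 were (random mean 2.34; 4224 as large). The random sets were not matched on the number of regions per gene. A gene with more control regions has more chances of a knockdown region, so this was not separated from more frequent sharing by naive genes. POU5F1, LIN28A, CRIPTO, GDF3, UTF1, DPPA4 and FGF4 had control promoter regions that no knockdown region overlapped. The OGT region was likewise not overlapped. DPPA4 nevertheless had 2 knockdown regions outside promoters, 1 of which overlapped a control region.

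The control list held 8977 distinct regions and the knockdown list 1334, a ratio of 6.73. Control regions covered 15.7 Mb and knockdown regions 1.04 Mb. The median width was 1577 bp in control (interquartile range 1245 to 2060) and 727 bp in knockdown (550 to 930). Promoter regions marked 3810 genes in control, 500 in knockdown and 395 in both. Among 20037 protein-coding genes, 14.9% had a promoter region in control and 2.04% in knockdown. These counts have no replicate check, and with unknown depth they compare the lists rather than the amount of OGA on chromatin.

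Of the control regions 901 overlapped a knockdown region by at least 1 bp (10.0%, Wilson 95% interval 9.43 to 10.7), whereas knockdown regions placed at random on the same chromosomes overlapped 0.198% on average and at most 0.312% in 100 placements. Of the knockdown regions 921 overlapped a control region (69.0%, 66.5 to 71.5), against 1.58% on average and at most 2.32% at random. Intervals cover counting error only. With only as many of the widest control regions as there were knockdown regions, the share of knockdown regions overlapping control was 17.8%.

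Histone genes kept regions most often among the fixed lists. Of their 33 genes with a control promoter region, 15 also had one in the knockdown list (45.5%), against a mean of 4.50 in random sets of control genes matched on region width, and 0 of 10000 such sets reached 15. All knockdown promoter regions at these histone genes lay on chromosome 6, which reflects the genes the list holds and is no result of the knockdown. The random sets were matched neither on chromosome nor on gene clustering, so neighbouring histone genes were not independent draws. The regions at H2AC17 (chromosome 6, 27887807 to 27893645) and H2AC4 (chromosome 6, 26031852 to 26036536) were overlapped by knockdown regions, while those at H3C11 and H4C6 were not. In the polycomb and DNA methylation list DNMT3B, DNMT3L, KDM2B and PHC1 had a promoter region in both lists (4 of 12, random mean 1.35; 398 of 10000 sets as large), and DNMT3L also belongs to the naive list and DNMT3B to the primed list. The knockdown region at KDM2B, however, overlapped no control region. Ribosomal protein genes had 3 of 30 in both lists, RPL27, RPS19 and RPSA, against a random mean of 3.36. Single genes of other lists with regions in both were SIN3A, PRKCZ, LDHB and E2F3, and for the respiratory chain ATP5F1B and ATP5MC1. In the knockdown list 0 genes of the trophectoderm, germ layer, 8-cell-like, fibroblast and olfactory receptor lists had a promoter region, and random lists had only 0.321 to 0.499 on average. Histone genes occur in similar copies, so the assignment of reads among them may be uncertain, which was not checked.

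The widest control promoter regions overlapped by a knockdown region were at SLC3A2, which encodes the heavy chain of amino acid transporters (chromosome 11, 62848717 to 62858551, 9835 bp), ARHGAP9 (6427 bp), C12orf57 (6423 bp) and H2AC17 (5839 bp). RPL23AP43, SNORA73B, TALAM1, RPL36AP44, LOC105371056 and H2AC4 completed the 10. The widest control promoter regions without overlap were a further region at SLC3A2 (chromosome 11, 62879127 to 62886060, 6934 bp), H3C11 (6640 bp) and RAB26 (6328 bp), followed by LOC105371520, CARHSP1, MIR7111, MIR141, ARHGDIA, ZNF48 and H4C6. The 5 widest knockdown promoter regions without overlap were narrower, at LOH12CR2 (chromosome 12, 12353032 to 12354924, 1893 bp), PCYT1A (1278 bp), PALD1 (1222 bp), the tRNA gene TRA-TGC2-1 (1178 bp) and AHSG (1155 bp).

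Promoters, taken as within 3 kb of a start site, held 46.9% of control regions (45.9 to 48.0) and 39.1% of knockdown regions (36.5 to 41.7). Within the control list the share was 47.4% among regions overlapped by the knockdown and 46.9% among the others. The knockdown list was less uniform. Knockdown regions that overlapped control lay at promoters in 45.4% and in introns in 26.2% of cases, whereas the 413 knockdown regions without overlap lay at promoters in 24.9% (21.0 to 29.3) and in introns in 50.1% (45.3 to 54.9). Their median distance to a start site was 11196 bp, against 3891 bp for overlapping knockdown regions and 3789 bp for control regions.

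**Figure D2:**
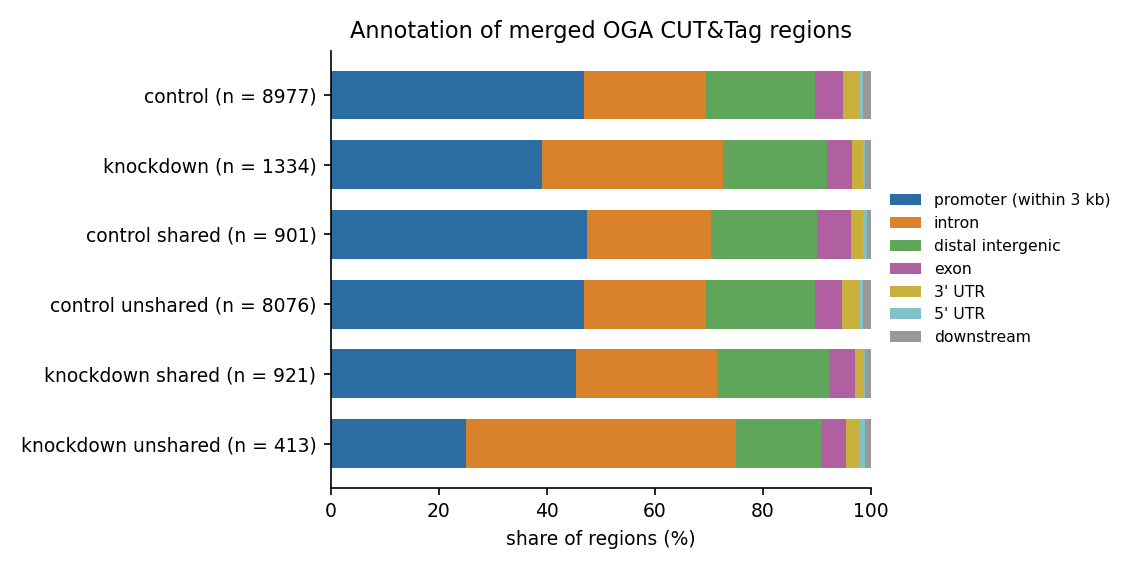
Share of regions (x axis, percent) in each annotation class for the control and knockdown lists and for the regions of each list that did (shared) or did not (unshared) overlap the other list, with n the number of regions. Intron regions made up 50.1% of knockdown regions without a control overlap and 26.2% of those with one.

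The locus of GDF3, DPPA3 and NANOG on chromosome 12 was mapped in full. The interval held 17 control regions and 1 knockdown region. The knockdown region lay in NANOG, which encodes a homeodomain factor of pluripotent cells, at 7790961 to 7791931 (971 bp), 1559 bp from the start site, and overlapped none of the control regions. It made NANOG the core pluripotency gene with a promoter region in the knockdown list.

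**Figure D3:**
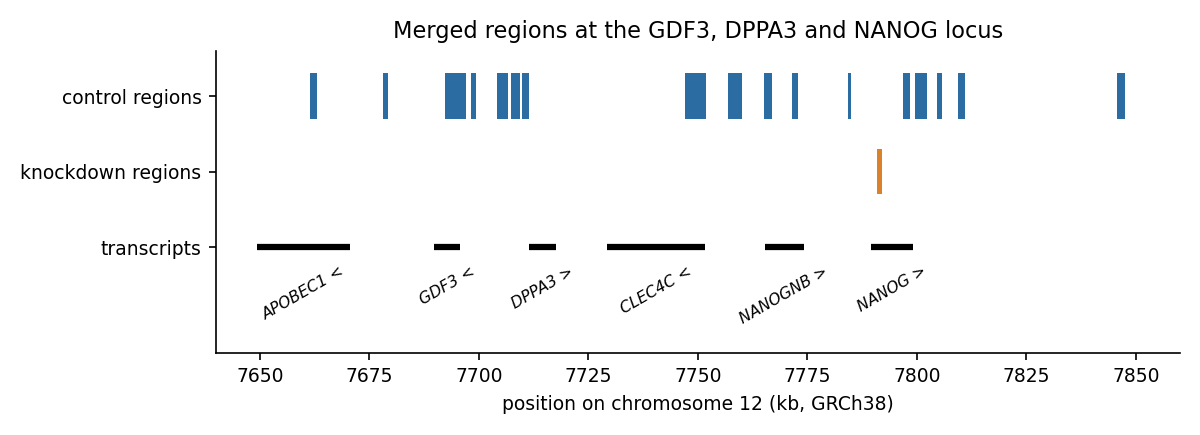
Map of merged regions at the GDF3, DPPA3 and NANOG locus of chromosome 12 (x axis, kb, GRCh38), with control regions in the top row, knockdown regions in the middle row and the transcripts named in the lists below, arrows giving their strand. The 17 control regions lay in and around GDF3, DPPA3 and NANOG, and the 1 knockdown region lay inside NANOG.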

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

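The tests of the number of regions were chosen after the result was seen. The numbers carried by the replicate peaks, which the comparisons above do not use, showed many peaks that entered no merged region. The highest peak number was 24287 and 28210 in control replicates 1 and 2 and 14203 and 13946 in knockdown replicates 1 and 2, a lower limit for the peaks called. Both control numbers lay above both knockdown numbers, and with 2 libraries per group an exact two-sided permutation test gave p = 0.333, the smallest this design allows. At least 14944 and 19054 control peaks and at least 12849 and 12590 knockdown peaks were thus in no listed region. At most 38.5% and 32.5% of control peaks entered the merged list, against at most 9.53% and 9.72% of knockdown peaks.

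The pattern to weigh was the smaller knockdown list. The lists differed 6.73-fold, while the highest peak numbers differed by 1.71 to 2.02 times, by 3.46 as the product over both replicates, and by 7.5 as that product times the ratio of median widths. Because a listed region needs a peak in each replicate and wide peaks meet more often, fewer peaks per knockdown replicate stay open as a cause. The products suppose that peaks of both replicates meet independently, which was not checked, and use widths after merging. They therefore set no firm limit. Narrower knockdown regions stay open too, since widths before merging are not listed: of 10 width classes of control regions, the widest was overlapped 2.41 times as often as the narrowest. Lower depth and less OGA on chromatin in the knockdown also stay open, and neither was tested.

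Uniform placement along the chromosomes does not account for the overlap of the knockdown regions with control regions. Of the knockdown regions 69.0% overlapped, against at most 2.32% in 100 random placements. The placements were not limited to promoters or accessible sites, so chance sharing among such sites was not tested. The regions the lists share may hold OGA left after knockdown or signal that does not depend on OGA. These explanations were not tested.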

How the results depend on the processing

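No paired analysis was possible because the lists merge both replicates, except for the highest peak numbers: control over knockdown was 1.86 as a ratio of means and 1.87 as the mean within replicate number (the block; exact two-sided sign-flip p = 0.5, the smallest 2 pairs allow), and 1.71 to 2.02 with a replicate left out. For the lists, leaving out a replicate, the count test and the motif analysis were not run. The block of peak numbers, random lists without length matching and the removal of histone genes were chosen after seeing the data. With regions at least as wide as the control median, 4496 control and 27 knockdown regions were left, 0.40% of control and 74.1% of knockdown regions overlapped, 1956 control, 10 knockdown and 5 common genes had a promoter region, and 4 lists, not 7, lay above the 97.5th percentile (without polycomb, glycolysis and cell cycle). The knockdown regions are narrower, so this filter by construction removed most of them. With equal numbers (1334 control regions) the overlap was 16.5% of control and 17.8% of knockdown regions, 48.7% of control regions lay at promoters, and 636 control and 85 common genes had one; polycomb and glycolysis left and O-GlcNAc cycling entered the lists above the 97.5th percentile. With centres within 500 bp the overlap was 7.75% and 52.2%. Promoters within 1 kb held 37.9% of control and 30.6% of knockdown regions, the naive list then leaving the set above the 97.5th percentile. With any region assigned to a gene, 6510 control, 1178 knockdown and 931 common genes were counted, and 10 lists lay above, with primed pluripotency, O-GlcNAc cycling and ERK, WNT, PKC and LIF signalling added. The other values stayed within their interval, or counts within 1.5 times, under these settings, under 50% overlap, on primary chromosomes, without length matching and without histone genes, though overlap settings and length matching by construction leave gene counts as they are; the 200 bp minimum removed nothing. Single-list counts moved in 21 of 32 cases with wide regions, 16 with any region, 14 with equal numbers, 4 with 1 kb promoters and 2 without histone genes. Unknown depth limits every count.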

Other observations

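The gene type, pathway and chromosome analyses were chosen after the lists were seen; for the chromosomes the rho and block tests were set after the uneven spread was noticed but before their results, and the check on chromosomes 8, 10, 13 and 15 after. Gene types were each set against random control genes, and not tested against each other. These random sets were not matched on region width, so gene type was not separated from width. Of 451 tRNA genes 45 had a promoter region in control and 3 in the knockdown, and 0 had one in both, where random sets of control genes gave 4.63 on average and 78 of 10000 gave as few. Of 10 snRNA genes with a control promoter region 4 also had one in the knockdown (145 of 10000 random sets as large). Long noncoding RNA genes had 26 of 434 in both lists (3 of 10000 random sets as small). For snoRNA genes it was 4 of 39 (random mean 4.0) and for miRNA genes 5 of 83 (random mean 8.63; 1280 as small), and protein-coding genes had 333 in both (random mean 309; 14 as large). Among the 108 pathways with at least 20 control genes, those with the most genes kept were Systemic lupus erythematosus (20 of 44) and Alcoholism (21 of 66), both of which contain histone genes, against 11.9% of all control genes with a pathway.

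Some genes carried a series of OGA regions. A4GALT, CECR2 and SUMO1P1 had 10 control regions each, SERINC5, TEAD4 and ZNF217 had 9, and JARID2 and MTA3 had 8. Knockdown regions overlapped 4 of the 10 at SUMO1P1 and 4 of the 9 at SERINC5, and 0 at TEAD4 and JARID2. TEAD4, a factor of the trophectoderm program, thus had 1 promoter region and 8 elsewhere. Counting any region assigned to a gene, the naive list had 18 of 29 genes in control and 8 in knockdown, and the core list 13 of 14 and 3.

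Promoter regions were unevenly spread over the chromosomes. In control 5.31% of protein-coding genes on chromosome 8 had one (Wilson 95% interval 3.90 to 7.21), 6.48% on chromosome 15, 6.51% on chromosome 13 and 6.95% on chromosome 10, against 20.7% on chromosome 6 and 20.3% on chromosome 19. The knockdown list ranged from 0.140% on chromosome 8 to 3.72% on chromosome 6. Peaks numbered in each control replicate were fewer on chromosomes 8, 10, 13 and 15 as a group, with 0.643 and 0.736 per protein-coding gene against 1.29 and 1.5 on the other chromosomes, and in the knockdown replicates 0.509 and 0.463 against 0.707 and 0.699. The match is not general, as chromosome 19 had 0.716 and 1.0 in control and 0.191 and 0.176 in knockdown, with 3.38% of its genes in the knockdown list. Chromosomes 16 (0.464 and 0.420), 17 (0.492 and 0.442) and 22 (0.404 and 0.350) were also below the group in the knockdown replicates. Within the group, chromosomes 13 (0.689 and 0.636) and 15 (0.637 and 0.562) were nearer the other chromosomes there. All these numbers are lower limits taken from listed peaks.

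Local runs of genes within blocks of 50 do not account for the spread. Of the variance of 390 blocks of 50 neighbouring genes, 25.0% lay between chromosomes, against at most 15.8% when blocks were dealt at random (permutation p = 0.0001, the smallest these permutations can give). Blocks were dealt singly, so runs longer than a block were not tested and stay open. Gene content is argued against less firmly: families that nearly all cells use followed the other genes over 23 chromosomes (Spearman's rho = 0.574, permutation p = 0.00481, adjusted p = 0.00481 over 3 relations; Pearson's r = 0.496, permutation p = 0.0165), and r = 0.411 without the 2 farthest chromosomes, no longer past the threshold (permutation p = 0.0648). On chromosomes 8, 10, 13 and 15, picked by their other genes, 12 of 95 family genes had a region (12.6%) against 200 of 777 elsewhere (25.7%; Fisher's exact p = 0.00497, over genes, which are not independent replicates). Copy number cannot be told apart from other properties that both lists share, since their shares followed each other (rho = 0.875, permutation p = 1e-05, the smallest possible, adjusted p = 3e-05; r = 0.884, permutation p = 1e-05; r = 0.882 without the 2 farthest) and no read depth was given. Region width also followed the share (rho = 0.662, permutation p = 0.0008, adjusted p = 0.0012; r = 0.605, permutation p = 0.00189; r = 0.569 without the 2 farthest), and base composition, mappability, a step of the submitters' processing, regions not analysed here and any biological explanation stay open as untested.

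A possible effect of width on the promoter share of control regions had nothing to explain: regions without a knockdown overlap differed from the others by -0.525 percentage points (95% interval -3.97 to 2.9), and by -0.945 with 10 width classes weighted equally.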
